A study of Homo sapiens with 21 samples.

How the data were processed

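RNA was sequenced from 21 libraries of KOLF2.2J-derived cells, 12 of the ExM scheme and 9 of the PrS scheme, collected on day 6. Per the labels, RNA was extracted with RNeasy Mini or NucleoSpin RNA Plus kits, libraries were made with KAPA RNA HyperPrep with RiboErase or Watchmaker kits with Polaris Depletion, and sequencing was done on a NovaSeq X. The labels list both extraction kits and both library kits for every sample and do not say which was used for which. The schemes differ in lane and index layout, so they were never fitted together. In the ExM scheme the word NEW stands in the names of the 9 KO libraries and not in those of the 3 WT libraries.

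Gene counts, the main measurement, were made by the authors with featureCounts and deposited as whole numbers that had not been normalized. Gene-level estimated counts and TPM were deposited by the authors from Salmon, and STAR is named beside them, per the submitters' processing notes. The genome build named there is GRCh38. Tool versions, the annotation release and the strand setting are not given in the sources used here, so counts of antisense and overlapping genes (AC008149.1 at ELK3, PINX1 at SOX7, INS-IGF2 at IGF2) and of near-identical copies (CSH, PSG, CGB and HLA genes) are uncertain. The deposited read statistics gave counts of unmapped, multimapping, no-feature and ambiguous reads per library. The rounded Salmon gene and transcript counts and the transcript estimated counts were not used here. Estimated counts were rounded to whole numbers before any count test.

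The count table held 38592 genes, of which 38568 matched a symbol by identifier, and 34390 had coordinates in GENCODE 29 (GRCh38), which gave the positions printed for genes and exons. Total gene counts per library were 19228244 to 26621980 in the ExM scheme and 23106193 to 26857365 in the PrS scheme. Reads assigned to genes made up 62.12% to 70.64% of each library and reads in no feature 14.84% to 24.77%. Mitochondrially encoded genes took 2.282% to 3.171% of gene counts and the 10 most abundant genes 5.06% to 11.31%.

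Differences were tested in R 4.3.3 with edgeR 4.0.16, as quasi-likelihood F-tests on the gene counts with TMM normalization, filterByExpr by group and robust dispersion estimates. All groups of a scheme entered 1 fit, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The filter left 18108 genes in the ExM scheme and 18316 in the PrS scheme. The common biological coefficient of variation was 0.127 and 0.113 with 8 and 6 residual degrees of freedom, and normalization factors ran from 0.98 to 1.029 and from 0.9 to 1.131. There were 5 comparisons of a KO with its WT and 4 between KO groups of a scheme. CPM values are gene counts per 1000000 TMM-scaled counts, and log2 CPM used a prior count of 2. On simulated counts with 200 changed genes, the test recovered 83.6% of 2-fold changes for SNAI2 KO against WT, 91% for ELK3 KO, 91% for SOX7 KO, 89.6% for ZNF175 KO and 94% for TFEB KO. Unchanged genes made up 2.9% (SOX7 KO) to 7.7% (ZNF175 KO) of the calls. The counts were drawn gene by gene, without variation shared by the genes of a clone, and only better-expressed genes were changed. They do not give the recovery in the real libraries.

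Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. There were 28 lists: syncytiotrophoblast, trophoblast progenitor, extravillous trophoblast, amnion, extraembryonic mesenchyme, epithelial junction, smooth muscle and cardiac, endothelial, pluripotency, primitive streak and mesoderm, endoderm, neural, lysosome and autophagy (CLEAR), MiT/TFE factors, Snail and Zeb factors, ternary complex and Ets factors, SOXF factors, immediate early and serum response, cell cycle, p53 targets, integrated stress and unfolded protein response, hypoxia, interferon, cholesterol synthesis, BMP and TGF-beta response, WNT response, imprinted, and mitochondrially encoded. Lists with fewer than 3 tested members got counts only, so 27 lists were tested in the ExM scheme and 28 in the PrS scheme. Some genes stand in more than 1 list, among them SNAI1, SNAI2, TWIST1, TWIST2, ZEB1 and ZEB2 in both the mesenchyme list and the list of Snail and Zeb factors.

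The genes named for a KO against WT followed a rule. It takes the targeted gene and, per direction, the 10 largest log2 fold changes among called genes with a mean log2 CPM of at least 1 and every KO library on the same side of all 3 WT libraries. It adds up to 4 called members, or the 2 of smallest p where none was called, of lists past the camera threshold, of the targeted factor's own family and of the lists closest to the scheme's cell types. Clone-style and LINC names, pseudogenes, and XIST and Y-linked genes were left out, and comparisons between KO groups took 5 genes per direction. The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Overlaps between comparisons that share WT libraries were set beside 50 simulations of unchanged groups against those libraries.

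Each result was recomputed with DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter at a mean CPM of 5, Salmon estimated counts, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, robust estimation off, only the 2 groups compared, and each library left out in turn. Added after the data were seen were the share of reads in no feature as a covariate, the syncytiotrophoblast list level as a covariate in the ExM scheme, and a fit without the 2 PrS libraries whose normalization factors lay farthest from 1.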

Results

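Gene expression was measured by RNA sequencing in 21 libraries of human cells that had been differentiated from the induced pluripotent stem cell line KOLF2.2J and collected on day 6. There were 2 differentiation schemes, both directed at cells of the early placenta. The ExM scheme makes extraembryonic mesenchyme, the connective tissue that fills the core of the placental villus, and the PrS scheme makes primitive syncytium, the fused, hormone-secreting trophoblast that first invades the uterine lining. In 5 groups a transcription factor gene had been disrupted on both alleles by an edit that introduces a premature termination codon. The ExM scheme held knockouts (KO) of SNAI2, ELK3 and SOX7, the PrS scheme held KO of ZNF175 and TFEB, and each scheme had its own wild-type (WT) group of the parental line. Every group had 3 libraries. The KO libraries of a group came from different clones, named here as in the labels (D12, E12 and G11 for SNAI2). The WT libraries came from replicate cultures numbered 1 to 3, so p-values measure the spread between these clones and cultures. No edited control clone is among the libraries. Effects of editing and of deriving a clone therefore cannot be told apart from those of losing the factor in any comparison with WT. Total gene counts ran from 19228244 in WT ExM 1 to 26857365 in TFEB KO A08.

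Within each scheme, a single axis held most of the variation between libraries. In the ExM scheme the leading principal component carried 70.4% of the variance of the 500 most variable genes, and clones of the same KO lay far apart on it, with ELK3 KO A05 at -24.12 and ELK3 KO C05 at 48.14. The next component carried 16.8% and set the 3 SNAI2 KO clones (-25.69 to -17.51) apart from the other 9 libraries (0.86 to 11.71). In the PrS scheme the leading component carried 73.5% and placed the TFEB KO clones (20.71 to 38.83) and the ZNF175 KO clones (-24.43 to -12.02) on opposite sides of the WT cultures (-9.92 to -9.06). Pairs of clones differed more than pairs of cultures. The chi-square per degree of freedom between libraries of a group ran from 2.22 for WT PrS 1 and 2 to 41.02 for TFEB KO A08 and A10, so none was a second sequencing of the same library.

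**Figure D1:**
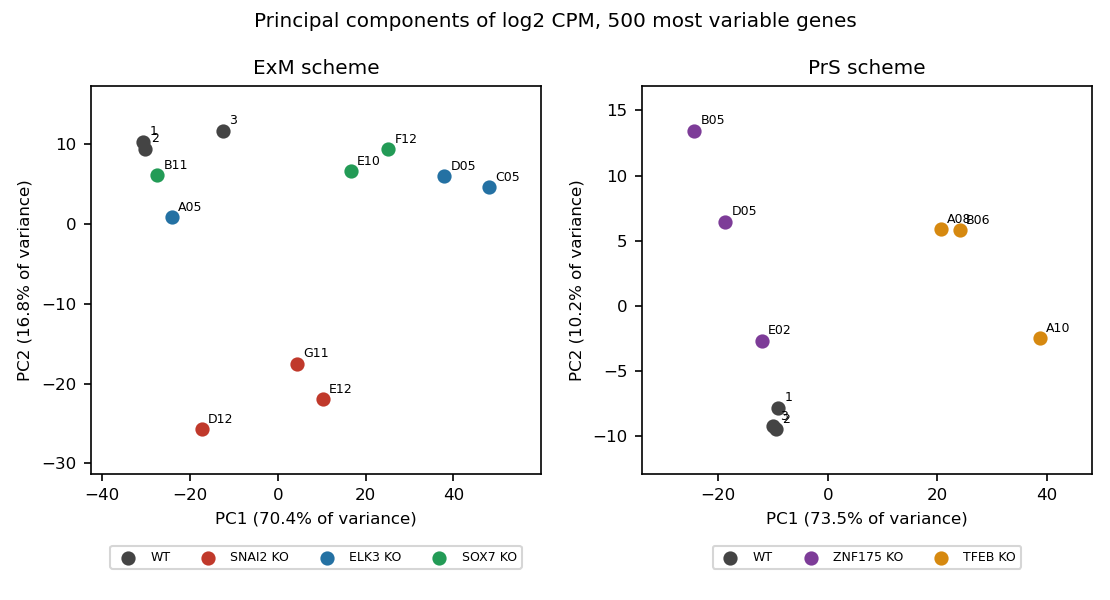
Principal components of log2 CPM (counts per 1000000 gene counts) for the 500 most variable genes, separately for the ExM scheme and the PrS scheme. Each point is a library, coloured by group and marked with its clone or culture; the axes give each component's share of the variance. SNAI2 KO clones lie apart on the vertical axis (-25.69 to -17.51), while clones of ELK3 KO and SOX7 KO are spread along the horizontal axis.

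The targeted genes come first, because they check the labels. The edit is a termination codon, which need not lower the mRNA, and mRNA of the targeted gene was lower in only 1 of the 5 knockouts. TFEB (ENSG00000112561, chromosome 6, 41683978 to 41736259, minus strand, GRCh38; edit at 41687966 to 41687968 in coding exon 6) fell from 77.4 ± 5.2 CPM (SD, n = 3) in WT to 33.8 ± 4.95 CPM in TFEB KO, a log2 fold change of -1.20 ± 0.12 (SE; edgeR adjusted p = 0.00015). Transcripts that carry the edit in their coding sequence made up 91.6% of TFEB TPM (transcripts per 1000000) in WT and 47% in TFEB KO. SNAI2 (ENSG00000019549, chromosome 8, 48917604 to 48921740, minus strand; edit at 48920308 to 48920310 in coding exon 2) rose from 99 ± 5.89 to 250 ± 16.5 CPM in SNAI2 KO (log2 fold change 1.34, edgeR adjusted p = 3.18e-06), and was 93.6 CPM in ELK3 KO and 100 CPM in SOX7 KO. SOX7 (ENSG00000171056, chromosome 8, 10723768 to 10730512, minus strand; edit at 10726512 to 10726514 in coding exon 2) rose from 23 ± 2.04 to 78.7 ± 29.8 CPM in SOX7 KO (log2 fold change 1.77 ± 0.23, edgeR adjusted p = 0.0429). Its call was lost without E10 (adjusted p = 0.166) and without WT 1, 2 or 3 (adjusted p = 0.2, 0.209 and 0.244), and SOX7 shares its locus with a read-through form of PINX1, so its counts are uncertain.

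ELK3 and ZNF175 mRNA did not differ from WT in their own knockouts at the threshold. ELK3 (ENSG00000111145, chromosome 12, 96194382 to 96269835, plus strand; edit at 96223684 to 96223686 in coding exon 2, where AC008149.1 overlaps) was at 186 ± 15.6 CPM in ELK3 KO and 194 ± 6.49 CPM in WT (log2 fold change -0.06, edgeR adjusted p = 0.615). Without C05 its log2 fold change was 0.02 (edgeR adjusted p = 0.943). It fell in SNAI2 KO, to 148 ± 7.76 CPM (log2 fold change -0.39, edgeR adjusted p = 0.000364). ZNF175 (ENSG00000105497, chromosome 19, 51571298 to 51592508, plus strand; edit at 51587010 to 51587012 in coding exon 5) was at 17.9 ± 3.5 CPM in ZNF175 KO and 10.8 ± 0.574 CPM in WT (log2 fold change 0.73, edgeR adjusted p = 0.149; 0.0309 with DESeq2). It rose in TFEB KO, to 23.3 ± 5.54 CPM (log2 fold change 1.10, edgeR adjusted p = 0.00252). RNA levels therefore do not by themselves check the labels of the SNAI2, ELK3, SOX7 and ZNF175 clones, because the edit leaves the gene in place. Library names of the SNAI2 KO clones read SNA1, while the labels give SNAI2 as the altered gene, so which gene was edited rests on the labels alone.

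**Figure D2:**
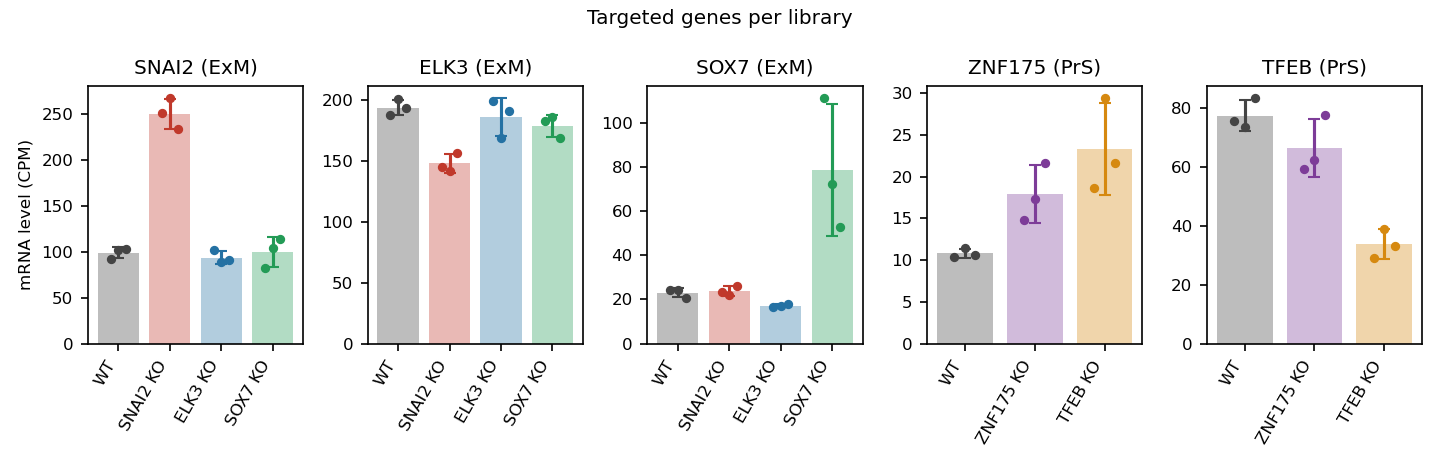
CPM of each targeted gene in every library of its scheme. Bars are group means, error bars are SDs over 3 libraries, and points are libraries. TFEB is lower in TFEB KO (33.8 against 77.4 CPM in WT), while SNAI2 and SOX7 are higher in their own knockouts (250 and 78.7 CPM).

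The WT cultures of the schemes carried the marker genes of different cell types. Of 32 syncytiotrophoblast genes at 1 TPM or more, 27 were higher in every PrS culture than in every ExM culture and 5 the reverse, against 5% each expected by chance. CGA, the common subunit of the glycoprotein hormones, was at 18700 ± 1400 TPM (SD, n = 3) in PrS and 28.3 ± 48.3 TPM in ExM, and CYP19A1, the aromatase, at 511 ± 10.5 and 3.47 ± 5.92 TPM. PrS cultures were also higher for 26 of 27 trophoblast progenitor genes (GATA3 427 against 44.7 TPM), 20 of 24 epithelial junction genes (CDH1, E-cadherin, 242 ± 12 against 123 ± 9.54 TPM) and 12 of 13 interferon genes. ExM cultures were higher for 19 of 30 extraembryonic mesenchyme genes and PrS cultures for 8, with the intermediate filament VIM at 2000 ± 58.4 against 44 ± 1.69 TPM and the collagen COL1A1 at 1490 ± 23.7 against 101 ± 8.31 TPM. They were also higher for 10 of 12 smooth muscle and cardiac genes (ACTC1 6890 against 1140 TPM), for all 4 primitive streak and mesoderm genes at 1 TPM and for all 3 neural genes at that level. ExM cells kept epithelial transcripts, with EPCAM at 195 ± 4.46 TPM. These values are set side by side with no test, since scheme and sequencing lane cannot be told apart.

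SNAI2 KO was compared with WT to see which genes depend on SNAI2, a zinc-finger repressor known from epithelial-mesenchymal transition. Epithelial genes rose in all 3 clones. ST14, the membrane protease matriptase, went from 2.33 ± 0.267 to 49.4 ± 9.24 CPM (SD, n = 3; log2 fold change 4.40 ± 0.31, edgeR adjusted p = 9.79e-06), and RAB25, a small GTPase of epithelial traffic, from 3.6 ± 0.604 to 42.4 ± 4.91 CPM. ITGB4, the hemidesmosome integrin, rose to 171 ± 29.8 from 13.6 ± 1.53 CPM. The other genes with the largest rises were BSPRY (log2 fold change 4.13), MACC1 (4.05), MAL2 (3.75), the ligand WNT7B (3.73), the keratin KRT80 (3.50), DAPP1 (3.45) and SLC7A4 (3.38). The largest falls included some genes of mesenchymal cells and their matrix. LOX, which crosslinks collagen, went from 324 ± 12.9 to 82.1 ± 18.7 CPM (log2 fold change -1.98 ± 0.22, edgeR adjusted p = 0.000302). The cadherin CDH6 went from 127 to 29.8 CPM, and the BMP antagonist GREM1 from 56.8 to 14 CPM. The E-cadherin repressor ZEB1 fell from 12 ± 0.429 to 3.02 ± 0.798 CPM. Further falls were in ATCAY (log2 fold change -2.78), ELFN1 (-2.34), DACT3 (-2.16), DYRK3 (-2.12), ADGRA2 (-2.03) and LRRC4B (-1.92).

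By gene list, 22 of 24 epithelial junction genes rose in SNAI2 KO and 0 fell (23 and 0 adjusted over the list alone), led by ST14, RAB25, CLDN7 (2.87) and TJP3 (2.85). The list passed the camera test (adjusted p = 7.37e-37, and 0.0319 with an estimated correlation). Of 29 extraembryonic mesenchyme genes 18 fell and 2 rose (the same counts adjusted over the list alone), with camera adjusted p = 7.39e-13 (adjusted p = 0.0119 with an estimated correlation). FOXF1 (-2.78, at 0.613 CPM in WT), ZEB1, the growth factor receptor PDGFRA (-1.87) and the matrix protein POSTN (-1.81) fell most, and SNAI2 itself, a member of the list, was among the 2 that rose. Per library, the mean log2 level of the epithelial list lay 1.52 to 1.73 above WT and that of the mesenchyme list 0.56 to 0.78 below it, in clones with little syncytiotrophoblast RNA (D12) and in those with more. Among the Snail and Zeb factors ZEB1 and ZEB2 (183 ± 3.28 to 77 ± 11.5 CPM) fell and SNAI2 rose, and the list of 7 did not pass (camera adjusted p = 0.5).

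Cholesterol synthesis genes were higher in SNAI2 KO for 16 of 17 members (16 adjusted over the list alone), by modest amounts: DHCR24 (log2 fold change 0.66), INSIG1 (0.65), MVD (0.54) and HMGCS1 (0.53), with camera adjusted p = 1.56e-10 (adjusted p = 0.0777 with an estimated correlation). Of 25 trophoblast progenitor genes 7 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000177, and 0.505 with an estimated correlation). KRT7, a keratin of trophoblast and other simple epithelia, rose from 452 ± 24.9 to 1000 ± 60.6 CPM, PPARG rose by 0.87 and SIGLEC6 by 4.81 from 0.0986 CPM, while the imprinted gene PEG10 fell (-0.77). Of 13 amnion genes VTCN1 (3.22), ITGB6 (34.6 to 292 CPM) and WNT6 (2.26) rose and SOX9 (-0.17) fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00443, and 0.497 with an estimated correlation). Of 13 extravillous trophoblast genes 0 rose and 6 fell, led by ITGA1 (278 to 107 CPM), PLAC8 (-0.61), MCAM (-0.50) and SERPINE2 (-0.47) (2 and 6 adjusted over the list alone; camera adjusted p = 0.0171, and 0.253 with an estimated correlation). The endothelial genes KDR (-2.57), ERG (-1.85) and FLI1 (-1.46) fell, 3 of 11 (4 adjusted over the list alone; camera adjusted p = 0.0127, and 0.12 with an estimated correlation). Of 16 imprinted genes 1 rose and 7 fell, among them MAGEL2 (-0.85), PLAGL1 (-0.62) and NNAT (-0.44) (1 and 8 adjusted over the list alone; camera adjusted p = 0.00937, and 0.0777 with an estimated correlation). The extravillous list, whose mean (-0.002) lay nearer 0 than its median (-0.35), no longer passed without D12 (adjusted p = 0.0549). The syncytiotrophoblast list did not pass (camera adjusted p = 0.17), with 2 genes higher and 1 lower of 30. Its level differed between clones, at -0.22 in D12, 2.15 in E12 and 1.80 in G11 against the WT mean on the log2 scale.

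In total 3759 of 18108 genes tested differed between SNAI2 KO and WT, 2020 higher and 1739 lower, of which 580 rose and 349 fell by 2-fold or more (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A fit of these 2 groups alone called 5658 and limma-trend on log2(TPM + 1) called 2509. All 9 KO library names of the ExM scheme carry the word NEW and the 3 WT names do not, so any batch that word stands for cannot be told apart from the KO against WT contrasts of this scheme.

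ELK3 KO was compared with WT to see which genes depend on ELK3, an Ets-family partner of serum response factor. The largest rises included epithelial genes here as well, by smaller amounts than in SNAI2 KO. ITGB4 went from 13.6 ± 1.53 to 62.6 ± 33.6 CPM (SD, n = 3; edgeR adjusted p = 0.0282), the receptor ERBB3 from 14.2 ± 1.89 to 56.4 ± 32.5 CPM, ST14 from 2.33 to 8.72 CPM and RAB25 from 3.6 to 13.2 CPM. The zinc transporter SLC30A2 (log2 fold change 3.42), TNS4 (2.29), the gap junction gene GJA5 (2.29), LAD1 (1.99), TMEM30B (1.93) and DAPP1 (1.89) completed the largest rises. Genes that fell included ZEB1 (12 ± 0.429 to 5.2 ± 0.31 CPM, log2 fold change -1.21), the protocadherin PCDH10 (56.8 ± 4.58 to 25.6 ± 2.43 CPM, edgeR adjusted p = 6.23e-05), the mechanosensitive channel PIEZO2 (-1.14) and the WNT antagonist DKK1 (-1.23). ATCAY (-1.76), F2RL2 (-1.47), DPYSL5 (-1.44), TRPC4 (-1.15), DPYD (-1.15) and FXYD6 (-1.09) also fell.

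In ELK3 KO 14 of 24 epithelial junction genes rose and 0 fell, with CLDN7 at 1.81 and CRB3 at 1.51 (21 and 0 adjusted over the list alone; camera adjusted p = 1e-20, and 0.281 with an estimated correlation). The list lay above WT by 0.45 in A05, 1.13 in C05 and 0.92 in D05, the same order as the syncytiotrophoblast level given below. Among 29 mesenchyme genes only ZEB1 passed (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.146; median -0.05, mean 0.07). The syncytiotrophoblast list passed (camera adjusted p = 1.19e-06; adjusted p = 0.487 with an estimated correlation) with 1 gene higher, TFPI2 (0.40), and 1 lower, PAPPA (-0.27), of 30 (15 and 1 adjusted over the list alone). Its level lay at -0.09 in A05, 4.25 in C05 and 3.75 in D05 against WT, and CGA was at 1.81, 1490 and 835 CPM in the same order. The trophoblast progenitor list passed beside it, with KRT7 (0.52) and KRT18 (0.51) higher and PEG10 (-0.64) lower of 25 (19 and 2 adjusted over the list alone; camera adjusted p = 1.19e-06, and 0.487 with an estimated correlation). The level of the progenitor list was 0.02 in A05, 1.98 in C05 and 1.60 in D05, following that of the syncytiotrophoblast list. Of 20 immediate early and serum response genes, the list closest to the known partner of ELK3, IER2 (0.68), JUNB (0.56), MCL1 (0.19) and EGR3 (1.51) rose and 0 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0244, and 0.444 with an estimated correlation). That list no longer passed without WT 3 (adjusted p = 0.115), and its level was 0.18 in A05, 0.53 in C05 and 0.47 in D05, following the syncytiotrophoblast level. Of the 9 ternary complex and Ets factors ETV5 fell (-0.54; camera adjusted p = 0.333), and of 11 endothelial genes KDR fell (-1.60; camera adjusted p = 0.485).

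Further list calls in ELK3 KO concerned 5 lists. Of 13 amnion genes ITGB6 (1.59) and WNT6 (1.37) rose (4 adjusted over the list alone; camera adjusted p = 0.000161, and 0.487 with an estimated correlation). Of 18 BMP and TGF-beta response genes ID4 (0.52) and ID3 (0.27) rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0244, and 0.497 with an estimated correlation). Of 47 lysosome and autophagy genes GAA (0.44) and PSAP (0.24) rose and RRAGD (-0.44) fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0107, and 0.654 with an estimated correlation). Of 17 cholesterol synthesis genes MSMO1 (-0.29) and CYP51A1 (-0.25) fell (3 adjusted over the list alone; camera adjusted p = 0.00552, and 0.497 with an estimated correlation). Of 16 imprinted genes PEG10, PLAGL1 (-0.76) and SGCE (-0.30) fell, with a median of -0.12 and a mean of 0.25 (4 adjusted over the list alone; camera adjusted p = 0.0244, and 0.281 with an estimated correlation). The lysosome list lay at 0 in A05, 0.20 in C05 and 0.18 in D05 and the amnion list at 0.41, 0.87 and 0.72, so both moved with the syncytiotrophoblast level. The imprinted list moved with it too, at -0.25, 0.41 and 0.28, and so lay above WT in C05 and D05 despite its negative median. Some of these list calls ended when a library was left out: BMP without A05 (adjusted p = 0.0863), WT 1 (0.0692) or WT 3 (0.0556), imprinted without A05 (0.282) or WT 1 (0.0555), and lysosome without D05 (0.0656). In total 994 of 18108 genes differed, 587 higher and 407 lower, of which 143 rose and 29 fell by 2-fold or more (edgeR, adjusted p below 0.05). That count was 3366 without A05, 216 without C05, 218 without D05, and 245, 258 and 208 without WT 1, 2 and 3. It was 1800 with DESeq2, 356 with limma-trend on log2(TPM + 1), and 236 with the syncytiotrophoblast level of each library as a covariate.

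SOX7 KO was compared with WT for the genes that depend on SOX7, an SRY-box factor of the F group. Few genes differed, and those with the largest rises besides SOX7 itself included DAPP1 (2.43 ± 0.538 to 8.39 ± 1.43 CPM; SD, n = 3; log2 fold change 1.79 ± 0.24, edgeR adjusted p = 0.0318), the ephrin receptor EPHA1 (1.11) and the desmosome plaque gene PKP3 (1.07). MYO5B (0.74), SFN (0.74), the epithelial protease PRSS8 (0.73), ODAPH (0.81), CDC42BPG (0.61), SLC27A6 (0.60) and KRT7 (452 ± 24.9 to 621 ± 39.5 CPM, edgeR adjusted p = 0.0318) rose too. PCDH10 fell from 56.8 ± 4.58 to 32.4 ± 2.99 CPM (log2 fold change -0.81 ± 0.09, edgeR adjusted p = 0.00522), as did the quinone reductase NQO1 (-0.39). Of 24 epithelial junction genes PRSS8 alone passed over all genes, and 17 were higher adjusted over the list alone (median 0.54; camera adjusted p = 1.81e-24, and 0.189 with an estimated correlation), with the list above WT by 0.41 in B11, 0.69 in E10 and 0.55 in F12.

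The syncytiotrophoblast level again differed between SOX7 KO clones, at -0.25 in B11, 2.83 in E10 and 3.18 in F12, with CGA at 0.0948, 261 and 551 CPM. No member of that list passed over all genes or adjusted over the list alone, though the list passed camera (adjusted p = 5.96e-08; adjusted p = 0.509 with an estimated correlation). Its members with the smallest p were KISS1 (1.07, edgeR adjusted p = 0.238) and PAPPA (-0.23, edgeR adjusted p = 0.353). Trophoblast progenitor genes behaved alike (0.19 in B11, 1.12 in E10 and 1.25 in F12), with KRT7 called (1 adjusted over the list alone; camera adjusted p = 5.96e-08, and 0.509 with an estimated correlation). Weak list calls, with 0 genes passing and 0 adjusted over the list alone, concerned 3 lists. Mesenchyme had a median of -0.09 and a mean of 0.04, with PDGFRB at -0.28 and KCNJ2 at -0.26 (camera adjusted p = 0.039, and 0.509 with an estimated correlation). Lysosome and autophagy genes included PSAP (0.16) and SGSH (0.23) (camera adjusted p = 0.0298, and 0.763 with an estimated correlation). Imprinted genes had a median of -0.12 and a mean of 0.06, with PEG10 at -0.21 and ZDBF2 at -0.15 (camera adjusted p = 0.0486, and 0.347 with an estimated correlation). Within that list F12 stood apart, with H19 at 1.24 CPM against 47.3 in B11, 170 in E10 and 118 to 127 in WT. IGF2 was at 80.6 CPM in F12, 9.72 in B11, 31 in E10 and 19.6 to 21.3 in WT. The mesenchyme call ended without B11, E10, WT 2 or WT 3 (adjusted p = 0.588, 0.0659, 0.267 and 0.197). The lysosome call ended without B11, E10, WT 1 or WT 3 (0.149, 0.155, 0.153 and 0.0965), and the imprinted call without B11, WT 1 or WT 2 (0.257, 0.153 and 0.0671). SOXF factors were represented by SOX7 only, since SOX17 and SOX18 fell below the count filter. The endothelial list did not pass (camera adjusted p = 0.911), with KDR at -0.55 and CDH5 at 2.10 (edgeR adjusted p = 0.566 and 0.61). In total 17 of 18108 genes differed, 15 higher and 2 lower (edgeR, adjusted p below 0.05; 1650 at an unadjusted p below 0.05). The count was 58 without B11, 3 without E10, 99 without F12, and 0, 2 and 1 without WT 1, 2 and 3. DESeq2 called 155 and limma-voom 2.

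The 3 knockouts of the ExM scheme were also compared with each other, in contrasts between KO libraries named alike. The WT libraries stayed in that fit and so entered its dispersions and filter. SNAI2 KO exceeded ELK3 KO for the basement membrane collagen COL4A4 (22.4 ± 1.73 against 2.46 ± 0.681 CPM; SD, n = 3; log2 fold change 3.17 ± 0.17, edgeR adjusted p = 7.31e-08), MACC1 (3.08), the growth factor TGFA (3.07), PRR36 (2.69) and MAL2 (2.68). It lay below ELK3 KO for the homeobox gene MEIS3 (-3.07), ADCY5 (-2.34), GSTA4 (-2.02), ELFN1 (-1.83) and ADGRA2 (-1.78). Against SOX7 KO it was higher for BSPRY (3.55), WNT7B (3.46), MACC1 (3.20), the endocytic receptor LRP2 (209 ± 59.2 against 25.6 ± 18.8 CPM) and ST14 (3.02). It was lower than SOX7 KO for ATCAY (-2.39), TLR4 (-2.13), LHX1 (-2.03), SFRP2 (-1.92) and ELFN1 (-1.87). ELK3 KO exceeded SOX7 KO for MEIS3 (1.79), RGL3 (1.16), RAB20 (0.79), WNT6 (0.77) and ADGRE5 (0.71). It was lower for SOX7 itself, KIAA1549L (-0.98), SALL1 (-0.80), EFNB1 (-0.65) and TMEM200A (-0.53). In total 2287 genes differed between SNAI2 KO and ELK3 KO (1292 higher and 995 lower in SNAI2 KO), 2551 between SNAI2 KO and SOX7 KO (1406 and 1145) and 30 between ELK3 KO and SOX7 KO (19 and 11 in ELK3 KO). The 2287 became 1397 without D12, 1306 without E12, 1294 without ELK3 KO D05 and 1398 with limma-trend. The 2551 became 1530 without E12 and 1672 with limma-trend. The 30 became 952 without A05, 0 without C05, 3 without ELK3 KO D05, 13 without B11, 6 without E10 and 474 without F12 (182 higher and 292 lower). They became 190 with DESeq2 (80 higher and 110 lower), 3 with limma-trend, 8 with robust estimation off and 0 with only these 2 groups in the fit.

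SNAI2 KO and ELK3 KO shared 713 genes called in the same direction, 423 higher and 290 lower, beside 65.5 and 39.1 expected of independent lists. Simulated unchanged groups set against the same WT libraries shared 0.04. Those groups held no changed genes, so a small overlap was built in. It does not show what shared controls add once many genes are called. Of the 17 genes called in SOX7 KO, 16 were called in the same direction in SNAI2 KO (14 higher and 2 lower, 1.7 and 0.2 expected of independent lists; 0.06 simulated) and 15 in ELK3 KO (14 and 1, 0.5 and 0 expected; 0.08 simulated). DAPP1, KRT7 and PCDH10 were among the genes that passed in all 3. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.605 between SNAI2 KO and ELK3 KO (0.5 simulated; covariance 0.2022 and 0.0429 simulated), r = 0.575 between SNAI2 KO and SOX7 KO (0.5; 0.1343 and 0.0429) and r = 0.823 between ELK3 KO and SOX7 KO (0.489; 0.2004 and 0.0424). With 3 WT libraries the controls could not be split into parts of at least 2, so part of each excess may come from the shared controls. The simulations gave clones and WT cultures the same spread per gene. Real WT pairs were closer (chi-square per degree of freedom 2.98 to 3.07) than pairs of clones (4.35 to 32.46), so the simulated values are rough references. The 9 KO library names also share the word NEW, and all 9 libraries come from edited clones while the WT cultures were not edited. Syncytiotrophoblast levels lay above the WT mean in clones of each knockout: 2.15 in E12 and 1.80 in G11, 4.25 in C05 and 3.75 in D05, 2.83 in E10 and 3.18 in F12. The remaining clone of each knockout lay at -0.22 (D12), -0.09 (A05) and -0.25 (B11). Their epithelial junction lists were still above WT, at 1.58, 0.45 and 0.41 (WT cultures -0.05 to 0.09). With 1 clone per knockout, that argues against syncytiotrophoblast RNA as the only source of the shared epithelial rise. For other shared genes it stays open. A response common to the knockouts cannot be told apart from the remaining sources here.

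**Figure D3:**
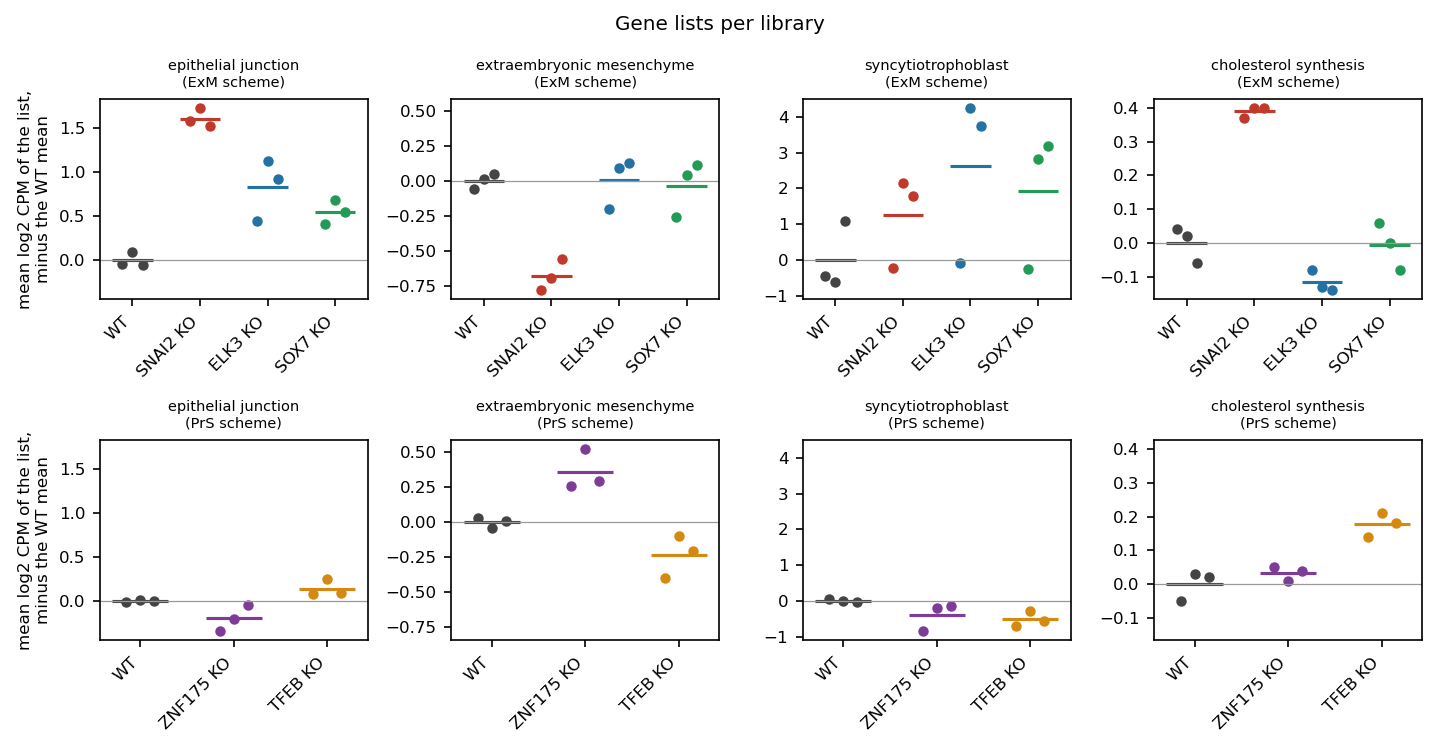
Mean log2 CPM of 4 gene lists in every library, minus the WT mean of the scheme, for the ExM scheme (upper row) and the PrS scheme (lower row). Points are libraries and lines are group means. Epithelial junction genes lie above WT in all 9 KO libraries of the ExM scheme (0.41 to 1.73), mesenchyme genes lie lowest in SNAI2 KO (-0.78 to -0.56), and syncytiotrophoblast genes spread from -0.25 to 4.25 between KO clones of the ExM scheme.

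TFEB KO was compared with WT of the PrS scheme for the genes that depend on TFEB, a basic helix-loop-helix factor known for lysosome and autophagy genes. The hormone gene CGA did not pass (5600 ± 426 to 5040 ± 1350 CPM, edgeR adjusted p = 0.757). Among the largest falls INSL4, a placental insulin-like peptide, went from 50.7 ± 0.513 to 2.68 ± 0.614 CPM (SD, n = 3; log2 fold change -4.23 ± 0.17, edgeR adjusted p = 2.19e-07). HSD11B2, which inactivates cortisol, went from 68.3 ± 4.09 to 3.65 ± 0.53 CPM (-4.22 ± 0.14, edgeR adjusted p = 4.97e-08), and the aromatase gene CYP19A1 from 672 ± 15.8 to 162 ± 28.1 CPM. The gastrin gene GAST (-5.22), TPPP3 (-5.01), TCL1B (45.5 to 3.48 CPM), the relaxin gene RLN2 (-3.58), GAL3ST1 (-3.30), CHST2 (49.9 to 5.39 CPM), RAB42 (-3.09) and SLC30A3 (-3.05) fell as well. Higher in TFEB KO were S100A9, a calcium-binding protein of myeloid and epithelial cells (0.43 ± 0.172 to 8.15 ± 3.1 CPM, log2 fold change 4.22 ± 0.35, edgeR adjusted p = 3.62e-05), the death ligand TNFSF10 (0.947 to 15.2 CPM), PADI1 (3.06), sarcolipin SLN (3.04), SYN2 (7.74 to 58.9 CPM), GPRC5C (19.6 to 142 CPM), the gluconeogenic enzyme FBP1 (2.72), CPLX1 (2.67) and ADAM18 (2.63).

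Among lysosome and autophagy genes of the CLEAR network, the known target set of TFEB, 7 of 47 fell and 0 rose (1 higher and 9 lower adjusted over the list alone). The 4 largest falls were in the coactivator PPARGC1A (4.11 to 2.05 CPM), GLA, alpha-galactosidase A (133 ± 2.38 to 72.4 ± 7.5 CPM), the Rag GTPase RRAGC (-0.62) and folliculin FLCN (-0.44). The list as a whole did not pass (median -0.03; camera adjusted p = 0.148), though it did without A10 (adjusted p = 0.0167). Of the MiT/TFE factors TFEB alone passed among 3 tested (camera adjusted p = 0.0728; 0.0167, 0.0349, 0.0225 and 0.0483 without A10, WT 1, WT 2 and WT 3). Of 32 syncytiotrophoblast genes 11 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 8.12e-10, and 0.292 with an estimated correlation), with INSL4, the fusogen ERVFRD-1 (175 to 38.8 CPM) and CYP19A1 falling most. CSH2 rose (1.99) from 0.403 CPM, uncertain because the CSH genes share sequence. Of 27 trophoblast progenitor genes KRT23 (244 to 660 CPM), TACSTD2 (0.75), PAGE4 (0.60) and 1 more rose, and CCKBR (301 to 135 CPM) and 1 more fell (camera adjusted p = 0.35). Extravillous trophoblast genes included 4 that rose and 0 that fell of 14: ASCL2 (1.96), MMP15 (365 to 655 CPM), NOTUM (0.76) and MMP2 (0.47) (6 adjusted over the list alone; camera adjusted p = 0.0218, and 0.516 with an estimated correlation). That call ended without A10 (adjusted p = 0.112).

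Hypoxia genes rose in TFEB KO for 8 of 16 members and fell for 1 (14 and 1 adjusted over the list alone), with EGLN3 at 89 ± 48.7 against 17.5 ± 1.7 CPM, NDRG1 at 66.2 ± 32.4 against 17.4 ± 1.91 CPM, ALDOC (1.68) and MXI1 (1.43), while VEGFA fell from 289 to 145 CPM. Camera gave adjusted p = 1.57e-06 (0.351 with an estimated correlation). The list lay above WT by 0.41 in A08, 1.26 in A10 and 0.65 in B06. The share of reads in no feature ran the other way, at 18.99%, 14.84% and 18.14% against 17.63% to 18.09% in WT, and A10 had the lowest normalization factor (0.9). A10 also lay farthest from WT for the WNT response list (0.11 in A08, 0.54 in A10 and 0.36 in B06) and the smooth muscle and cardiac list (-0.70, -1.36 and -0.52). In the same order, so it did for the immediate early (0.41, 0.75 and 0.51), imprinted (0.26, 0.59 and 0.28) and amnion lists (0.33, 0.68 and 0.44). The SOXF (0.45, 1.09 and 0.65) and extravillous lists (0.17, 0.61 and 0.26) did likewise. For the syncytiotrophoblast list A10 lay nearest WT (-0.71, -0.27 and -0.57). Immediate early genes rose for 7 of 19 and fell for 1, led by EGR3 (2.25), FOS (1.88), DUSP6 (1.62) and DUSP4 (1.46) (8 and 1 adjusted over the list alone; camera adjusted p = 1.69e-05, and 0.261 with an estimated correlation). WNT response genes rose for 5 of 10, among them NKD1 (1.39), TNFRSF19 (17.2 to 39.7 CPM), APCDD1 (0.87) and NOTUM (5 adjusted over the list alone; camera adjusted p = 0.0218, and 0.261 with an estimated correlation). Cholesterol synthesis genes rose for 6 of 18, with LDLR (0.95), DHCR7 (0.69), INSIG1 (0.60) and HMGCS1 (0.36) (6 adjusted over the list alone; camera adjusted p = 0.00762, and 0.261 with an estimated correlation). Imprinted genes rose for 4 of 16: PLAGL1 (1.35), PHLDA2 (0.78), H19 (1670 to 2900 CPM) and IGF2 (762 ± 26.2 to 2040 ± 807 CPM), which overlaps INS-IGF2 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00898, and 0.351 with an estimated correlation). For p53 targets 4 of 18 rose and 1 fell, with CDKN1A (245 to 435 CPM), FDXR (0.62), BBC3 (0.56) and SESN1 (0.44) higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.029, and 0.261 with an estimated correlation). The p53 call ended without A08 or WT 2 (adjusted p = 0.065 and 0.0508).

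Further lists passed the camera threshold in TFEB KO. Of 14 amnion genes CDX2 (2.25), TFAP2B (1.75), IGFBP5 (1.37) and VTCN1 (0.41) rose (4 adjusted over the list alone; camera adjusted p = 0.00762, and 0.261 with an estimated correlation), and of 3 SOXF factors SOX18 (1.83) rose (1 adjusted over the list alone; camera adjusted p = 0.0321, and 0.292 with an estimated correlation). Of 16 BMP and TGF-beta response genes 5 rose, with SMAD9 (1.40), TGFBI (0.95) and ID3 (0.53), and 2 fell, with ID2 (-0.74) (the same counts adjusted over the list alone; camera adjusted p = 0.0416, and 0.488 with an estimated correlation). Lower were the smooth muscle and cardiac genes NKX2-5 (-2.99 from 0.989 CPM) and MYL4 (-0.80) of 15 (5 adjusted over the list alone; camera adjusted p = 0.00032, and 0.351 with an estimated correlation). Of 7 Snail and Zeb factors ZEB1 (-2.31 from 0.349 CPM), TWIST1 (-1.37) and TWIST2 (-1.16) fell (4 adjusted over the list alone; camera adjusted p = 0.00442, and 0.261 with an estimated correlation). Of 5 neural genes TUBB3 fell from 336 to 168 CPM (1 adjusted over the list alone; camera adjusted p = 0.0147, and 0.261 with an estimated correlation). Interferon genes OAS1 (-0.83), OAS3 (-0.65) and STAT1 (-0.37) fell of 14 tested (5 adjusted over the list alone; camera adjusted p = 0.00499, and 0.366 with an estimated correlation). Of 24 cell cycle genes RRM2 (-0.79) fell (1 adjusted over the list alone; camera adjusted p = 0.01, and 0.488 with an estimated correlation). Of 13 mitochondrially encoded transcripts 0 passed, with MT-ND2 at -0.32 and MT-ND3 at -0.24 (edgeR adjusted p = 0.0757 and 0.0816; 0 adjusted over the list alone; camera adjusted p = 0.0199, and 0.488 with an estimated correlation). The SOXF and cell cycle calls ended without A10 (adjusted p = 0.0766 and 0.0611), and the BMP call without A10, WT 1, WT 2 or WT 3 (0.406, 0.0593, 0.129 and 0.0526). In total 2357 of 18316 genes differed between TFEB KO and WT, 1360 higher and 997 lower (edgeR, adjusted p below 0.05). The count was 1558 without B06 and 1097, 1065 and 1144 without WT 1, 2 and 3. It was 4399 (2326 higher and 2073 lower) with the share of reads in no feature as a covariate, and 3643 without the 2 PrS libraries whose normalization factors lay farthest from 1, ZNF175 KO B05 and TFEB KO A10.

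ZNF175 KO was compared with WT for the genes that depend on ZNF175, a KRAB zinc-finger protein. No gene passed edgeR's quasi-likelihood test at an adjusted p below 0.05 (smallest adjusted p 0.0788), with 3058 of 18316 genes at an unadjusted p below 0.05. The count was 249 with DESeq2, 0 with limma-voom, 0 with limma-trend on log2(TPM + 1), and 131 without a filter on low counts. It was 868 without E02, 2 without D05, 600 without both B05 and TFEB KO A10, and 54 with the share of reads in no feature as a covariate. Genes of smallest p included VIM, at 34.9 ± 12.1 CPM in ZNF175 KO and 13.6 ± 0.124 CPM in WT (SD, n = 3; log2 fold change 1.36 ± 0.22, edgeR adjusted p = 0.0788), the collagen COL5A2 (152 ± 7.76 and 112 ± 2.63 CPM, edgeR adjusted p = 0.0788) and the homeobox gene MSX1 (15.2 ± 2.7 and 8.31 ± 0.114 CPM, edgeR adjusted p = 0.0788).

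Adjusted over the list alone, 17 of 30 mesenchyme genes were higher in ZNF175 KO and 0 lower (camera adjusted p = 1.46e-08; adjusted p = 0.358 with an estimated correlation). The same held for 5 of 15 smooth muscle and cardiac genes, with MYL4 at 1.10 and DES at 1.63 (edgeR adjusted p = 0.102 and 0.137; camera adjusted p = 1.82e-08, and 0.358 with an estimated correlation). Of 16 BMP and TGF-beta response genes 7 were higher on the same terms, among them MSX1 and ID3 (0.54) (camera adjusted p = 0.00103, and 0.358 with an estimated correlation). So were 3 of 9 ternary complex and Ets factors, with ETS1 at 0.91 and ELK3 at 0.71 (edgeR adjusted p = 0.139 and 0.146; camera adjusted p = 0.0163, and 0.358 with an estimated correlation), and 3 of 14 amnion genes, with HAND1 at 0.41 and BAMBI at 0.49 (camera adjusted p = 0.00872, and 0.358 with an estimated correlation). The p53 list leaned higher with 0 members passing, ZMAT3 at 0.47 and XPC at 0.25 (camera adjusted p = 0.0335, and 0.358 with an estimated correlation). Integrated stress and unfolded protein response genes were lower for 3 of 18 adjusted over the list alone, with SLC7A11 at -0.34 and TRIB3 at -0.35 (edgeR adjusted p = 0.155 and 0.182; camera adjusted p = 8.81e-07, and 0.358 with an estimated correlation). No member of the other lower lists passed, over all genes or adjusted over the list alone. These were syncytiotrophoblast, with INSL4 at -0.39 and OVOL1 at -0.41 (camera adjusted p = 2.49e-08, and 0.358 with an estimated correlation), and trophoblast progenitor, with ELF5 at -0.69 and PAGE4 at -0.53 (camera adjusted p = 5.53e-05, and 0.382 with an estimated correlation). Epithelial junction followed, with CLDN4 at -0.35 and CLDN7 at -0.27 (camera adjusted p = 1.87e-05, and 0.358 with an estimated correlation), as did lysosome and autophagy, with CLCN7 at -0.27 and GLA at -0.41 (camera adjusted p = 1.37e-05, and 0.452 with an estimated correlation). The last were mitochondrially encoded, with MT-ND4L at -0.23 and MT-ATP8 at -0.25 (camera adjusted p = 7.4e-05, and 0.358 with an estimated correlation), and extravillous trophoblast, with PLAC8 at 0.93 and HLA-G at -0.43 (camera adjusted p = 0.0335, and 0.613 with an estimated correlation). The extravillous call ended without B05 or WT 1 (adjusted p = 0.316 and 0.0614), the p53 call without D05, E02 or WT 2 (0.075, 0.169 and 0.0663) and the amnion call without E02 or WT 2 (0.0826 and 0.0651). The share of reads in no annotated feature, which was 17.63% to 18.09% in WT, was 24.77% in B05, 20.57% in D05 and 16.82% in E02. In the same order the syncytiotrophoblast list lay at -0.85, -0.21 and -0.15 against WT, the progenitor list at -0.59, -0.24 and 0.07, and the epithelial list at -0.34, -0.20 and -0.04, so B05 carried most of these falls. Other lists followed that order too, with integrated stress at -0.61, -0.24 and -0.17, lysosome and autophagy at -0.25, -0.12 and -0.02, and smooth muscle and cardiac at 1.02, 0.92 and 0.25.

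Between ZNF175 KO and TFEB KO, 4740 genes passed the threshold, 2177 higher and 2563 lower in ZNF175 KO (edgeR, adjusted p below 0.05). On log2(TPM + 1) with limma-trend, where the median of all genes was 0.115 against 0.033 in edgeR, the split was 1864 higher and 1337 lower. Higher in ZNF175 KO were GAST (6.16 against 0.189 CPM), TPPP3 (log2 fold change 4.50), the collagen COL8A1 (11.1 ± 5.38 against 0.62 ± 0.422 CPM; SD, n = 3), INSL4 (3.84 ± 0.17, edgeR adjusted p = 6.15e-07) and HSD11B2 (3.78 ± 0.14, edgeR adjusted p = 1.62e-07). Lower were S100A9 (-3.87), TNFSF10 (-3.65), SYN2 (-3.04), FBP1 (-3.03) and WNT1 (1.81 ± 0.941 against 14.7 ± 5.94 CPM). No gene was called in both comparisons with WT, where ZNF175 KO had 0 calls. Across genes the log2 fold changes correlated with r = 0.035, beside 0.506 between simulated unchanged groups with shared controls. Their covariance was 0.0062 beside 0.0304 simulated. The simulation gave clones and WT cultures the same spread per gene. Real WT pairs were closer (chi-square per degree of freedom 2.22 to 2.78) than pairs of clones (5.52 to 41.02). The simulated values may therefore be too high, and the gap to the real ones decides nothing. The 4740 became 3115 without B05, 3072 without D05 and 2684 with only these 2 groups in the fit.

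**Figure D4:**
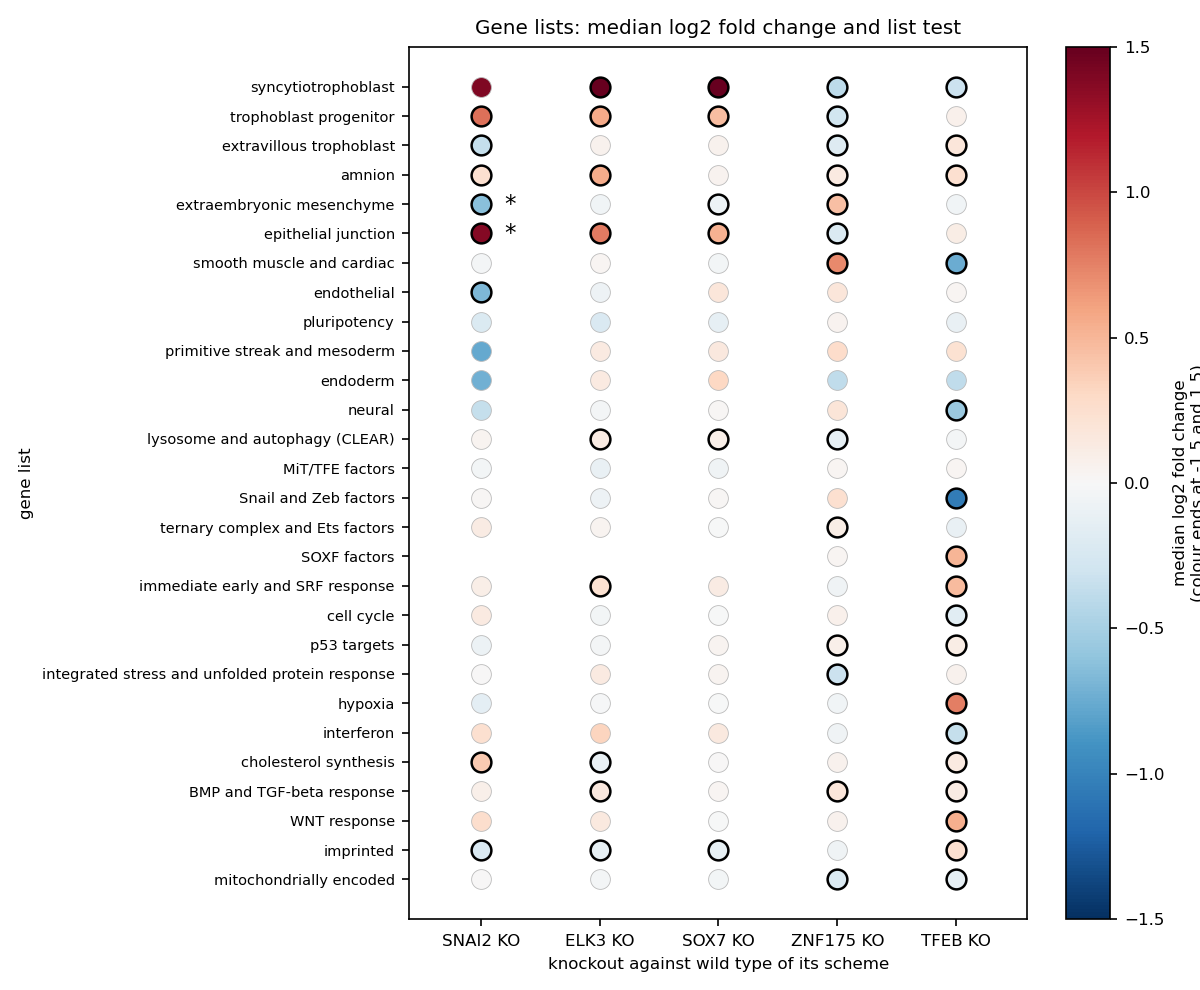
Median log2 fold change of 28 gene lists in each knockout against the WT of its scheme. Rows are lists, columns are knockouts, colour is the median log2 fold change (red higher, blue lower, colour ends at -1.5 and 1.5), a black rim marks lists past the camera threshold at the preset correlation, and an asterisk marks those that also pass with an estimated correlation. Only epithelial junction and extraembryonic mesenchyme in SNAI2 KO carry an asterisk (adjusted p = 0.0319 and 0.0119).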

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

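Tests of carry-over, cell mixture, RNA quality and shared preparation were chosen only after the result was seen, and those of the targeted genes' regions and of other splits of the libraries before it.

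Direct contrasts between knockouts of a scheme, each a test of the difference between their effects against the same WT, found 2287 genes for SNAI2 KO and ELK3 KO, 2551 for SNAI2 KO and SOX7 KO, 30 for ELK3 KO and SOX7 KO, and 4740 for ZNF175 KO and TFEB KO. The 2287 genes became 1397 without D12, 1306 without E12 and 1294 without ELK3 KO D05, and the 2551 became 1530 without E12. The 30 genes became 952 without A05, 0 without C05, 3 without ELK3 KO D05, 13 without B11, 6 without E10 and 474 without F12. The 4740 became 3115 without B05 and 3072 without ZNF175 KO D05. In the read statistics every SNAI2 KO and every ELK3 KO library had a higher share of multimapping reads than every WT library of the ExM scheme (means 6.12% and 7.19% against 5.64%), among 20 shares compared, where chance gives 5% of each in a direction. In 3 more, all unmapped reads, every KO library lay below every WT library (ELK3 KO 3.92% against 4.9%, ZNF175 KO 2.81% and TFEB KO 2.57% against 3.02%).

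Syncytiotrophoblast genes differed between clones of the same knockout in the ExM scheme, with CGA at 1.81 CPM in ELK3 KO A05 and 1490 CPM in C05, and between WT cultures as well, at 20.4 CPM in WT 3 against 0.202 and 0.038 CPM in WT 1 and 2. Reads carried over from a PrS library would put all of its abundant genes at 1 common share. For every donor and each of the 6 libraries with a median share over 1%, at least 3 of 18 genes lay off that share. In ELK3 KO C05 and D05 these were 5 to 9 genes, at median shares of 9.08% to 27%. That argues against whole carry-over into C05 and D05 from any of the 9 PrS libraries. The count does not decide for the lower shares of SNAI2 KO and SOX7 KO clones. ELK3 KO A05, with almost none of this RNA, had 3 to 8 genes off as well. The spread of the shares (lowest quartile ratio 1.59) decided nothing by itself. All 20 abundant PrS genes were above 3 counts in each of those libraries (fewest 20), at median levels of 1.29% to 17% of those of WT PrS, but the libraries were picked by the same genes, so this does not decide whether syncytiotrophoblast-like cells are the source. The share of reads in no feature took up 40.4% of the variance within groups (permutation p = 0.0918 over 1296 arrangements). Libraries of like share differed in list level, with WT 2 (17.25%) at -0.63 and ELK3 KO C05 (17.31%) at 4.25. SOX7 KO B11 (20.56%) lay at -0.25 and SNAI2 KO E12 (20.65%) at 2.15. The share alone therefore does not set the level across groups. A part played by RNA quality in the spread within groups cannot be told apart. Partial carry-over, an outside donor and a programme switched on within the mesenchymal cells also stay open, and no biological explanation was tested beyond the groups.

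In SNAI2 KO epithelial junction genes were higher and mesenchyme genes lower than in WT. A preparation shared by the knockout libraries would not separate SNAI2 KO from the other knockouts, yet the epithelial median was 0.69 higher (log2) than in ELK3 KO and 1.05 higher than in SOX7 KO, with 18 and 19 of 24 genes called, while the smaller rise common to all 3 knockouts stays confounded with it. Syncytiotrophoblast-like cells as the source of the epithelial genes are argued against by 22 genes still called higher with the syncytiotrophoblast level as a covariate (median 1.38 before and 1.40 after). Dilution of mesenchyme genes by such cells is argued against by their median, which was -0.625 before and -0.773 with that covariate, with 18 of 29 genes called lower. Loss of SNAI2 repression of epithelial genes may be a cause and was not tested.

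SNAI2 and SOX7 mRNA were higher in their own knockouts. A gain of the surrounding region would raise its other genes too. The median log2 fold change of tested genes within 1 Mb was -0.03 around SNAI2 (4 genes, 1 called higher) and -0.04 around SOX7 (18 genes, 0 called higher). That argues against a gain of the whole region, weakly for SNAI2 with so few genes. A gain of the gene alone would not show in these medians. Reads of the overlapping PINX1 read-through gene counted for SOX7 would be assigned elsewhere by a transcript-level method, but the SOX7 change was 1.774 in Salmon estimated counts. Loss of negative feedback of each factor on its own gene may be a cause and was not tested. The SOX7 call itself was lost without E10 (adjusted p = 0.166) and without WT 1, 2 or 3 (adjusted p = 0.2, 0.209 and 0.244).

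Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. As many genes as in the real split came from 1 of 10 splits, the real one, for SNAI2 KO (3759, highest other 0), ELK3 KO (994, highest other 0), SOX7 KO (17, highest other 0) and TFEB KO (2357, highest other 0) against WT, and for SNAI2 KO against ELK3 KO (2287, highest other 0), SNAI2 KO against SOX7 KO (2551, highest other 0) and ZNF175 KO against TFEB KO (4740, highest other 0). For ZNF175 KO against WT, with 0 genes, all 10 splits gave as many (highest other 0). For ELK3 KO against SOX7 KO, 2 splits gave 30 genes or more, and the highest other gave 892 with A05, B11 and E10 on 1 side. Their syncytiotrophoblast levels (-0.09, -0.25 and 2.83) lay below those of C05, D05 and F12 (4.25, 3.75 and 3.18). That points to a structure of the samples other than the groups, which in this split follows the syncytiotrophoblast level.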

How the results depend on the processing

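Alternatives chosen after the data were seen are the no-feature share and the syncytiotrophoblast level as covariates, and the fit without ZNF175 KO B05 and TFEB KO A10. No paired analysis was possible because clone names do not match the numbers of the WT cultures. The cause of each change below was not tested unless stated.

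For the 994 genes of ELK3 KO against WT, DESeq2 gave 1800, limma-trend on log2(TPM + 1) 356, the no-feature covariate 635 and the syncytiotrophoblast covariate 236, and leaving out libraries 208 (WT 3) to 3366 (A05). For the 17 of SOX7 KO, DESeq2 gave 155, limma-voom 2, no filter 84, limma-trend 6, robust off 5, only the 2 groups 89, the no-feature covariate 5, the syncytiotrophoblast covariate 32, and leaving out libraries 0 (WT 1) to 99 (F12). For the 3759 of SNAI2 KO, only the 2 groups gave 5658, and leaving out libraries 2538 to 3199. For SNAI2 KO against ELK3 KO (2287) limma-trend gave 1398 and leaving out libraries 1294 to 3407. For SNAI2 KO against SOX7 KO (2551) limma-trend gave 1672 and leaving out libraries 1530 to 2617. For ELK3 KO against SOX7 KO (30) DESeq2 gave 190, no filter 109, limma-trend 3, robust off 8, only the 2 groups 0, the no-feature covariate 59, the syncytiotrophoblast covariate 166, and leaving out libraries 0 (C05) to 952 (A05).

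For the 0 genes of ZNF175 KO against WT (3058 at an unadjusted p below 0.05 in edgeR), DESeq2 gave 249, no filter 131, the no-feature covariate 54, the fit without B05 and A10 600, limma-voom and limma-trend 0, and leaving out libraries 0 to 868 (E02). For the 2357 of TFEB KO, the no-feature covariate gave 4399, the fit without B05 and A10 3643, and leaving out libraries 1065 (WT 2) to 2663. For ZNF175 KO against TFEB KO (4740), only the 2 groups gave 2684 and leaving out libraries 3072 (D05) to 5614.

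Lists past the threshold fell with an estimated correlation to 2 from 8 in SNAI2 KO, and to 0 from 9 in ELK3 KO, 6 in SOX7 KO, 13 in ZNF175 KO and 17 in TFEB KO. They were 5 with limma-trend in SNAI2 KO and 11 with a mean CPM of at least 5 in TFEB KO. Leaving out libraries gave 8 to 10 in SNAI2 KO, 7 to 9 in ELK3 KO, 4 to 7 in SOX7 KO, 11 to 13 in ZNF175 KO and 15 to 19 in TFEB KO. Calls shared in the same direction vary with the threshold by construction. At an adjusted p of 0.01 and 0.1 they were 146 and 1386 (713 at 0.05) for SNAI2 KO and ELK3 KO. They were 1 and 42 (16) for SNAI2 KO and SOX7 KO, and 1 and 40 (15) for ELK3 KO and SOX7 KO. For ZNF175 KO and TFEB KO they were 7 at 0.1 (0 at 0.05), while 10 genes were called in opposite directions at 0.1.

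Directions reversed for 7 results, of which only the syncytiotrophoblast list in SOX7 KO had passed the threshold in edgeR or camera. For lists the direction is that of camera, which can turn while the median keeps its sign. The endothelial list in SOX7 KO gave a median of 0.001 with DESeq2, 0.039 with no filter, -0.144 with limma-trend, -0.037 with the syncytiotrophoblast covariate, and over libraries left out -0.213 (B11) to 0.364 (E10), with -0.087 without F12. In ELK3 KO that list gave 0.162 with a mean CPM of at least 5 and 0.07 with limma-trend. The syncytiotrophoblast list in SOX7 KO gave 0.013 with its own level as a covariate, by construction. The trophoblast progenitor list in TFEB KO gave -0.062 without A10 and also without B05 and A10, and up to 0.17 (A08) without other libraries. SGSH in SOX7 KO gave -0.085 with limma-trend, MT-ND3 in TFEB KO 0.001 with Salmon counts, and ELK3 in ELK3 KO -0.116 (A05) to 0.015 (C05) over libraries left out.

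Of 264 values of named genes, 259 kept direction and side of the threshold with DESeq2 size factors, 250 with DESeq2, 230 with limma-voom and 260 with Salmon counts. With limma-trend 202 did, 48 lost their call and 1 reversed, and the rest were not tested there because of its TPM filter. Leaving out libraries kept 1193 values, while 370 lost their call and 20 gained one. Epithelial junction and mesenchyme lists in SNAI2 KO passed without any single library at the preset correlation. The test with an estimated correlation was not repeated with libraries left out. The lowest depths were 19228244 gene counts in the ExM scheme and 23106193 in the PrS scheme. They leave genes below about 1 CPM, such as ZEB1 in the PrS scheme (0.349 CPM), the least precise.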

Other observations

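Genes of this part were named after their values were seen, and no test of an explanation was made. Pluripotency genes moved both ways in SNAI2 KO: the RNA-binding protein gene LIN28A fell from 45.5 ± 2.7 to 17.9 ± 1.78 CPM (SD, n = 3; log2 fold change -1.35, edgeR adjusted p = 5.74e-05), while L1TD1 rose from 93.8 ± 3.05 to 188 ± 8.74 CPM and TDGF1, a Nodal co-receptor, from 27.1 ± 1.87 to 67.5 ± 3.95 CPM. Of 12 tested, 2 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.728). L1TD1 also rose in ELK3 KO (140 ± 8.3 CPM, edgeR adjusted p = 0.000155), where USP44 fell (camera adjusted p = 0.275 for the list). The list did not pass in SOX7 KO (0.318), ZNF175 KO (0.362) or TFEB KO (0.329).

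Endoderm genes included FOXA1, a pioneer factor, which rose in TFEB KO from 2.31 ± 0.208 to 8.15 ± 1.89 CPM (edgeR adjusted p = 0.000271), and TTR, the transthyretin gene, which fell from 5.11 ± 0.303 to 1.31 ± 0.12 CPM (edgeR adjusted p = 3.55e-05). The list did not pass in any comparison (camera adjusted p = 0.111 in TFEB KO, 0.5 in SNAI2 KO, 0.525 in ELK3 KO, 0.863 in SOX7 KO and 0.503 in ZNF175 KO). Among primitive streak and mesoderm genes FOXC1 fell in SNAI2 KO (-1.01) and rose in TFEB KO (1.75), and that list did not pass either (camera adjusted p = 0.0766 in SNAI2 KO, 0.925 in ELK3 KO, 0.611 in SOX7 KO, 0.104 in ZNF175 KO and 0.42 in TFEB KO). In SNAI2 KO 8 of 18 p53 targets fell by small amounts (MDM2 -0.23, FDXR -0.37) and 1 rose (camera adjusted p = 0.175), and 5 of 16 hypoxia genes fell while EGLN3 rose (1.37; camera adjusted p = 0.0766).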
